A study of Macaca mulatta with 32 samples.

How the data were processed

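The series holds 32 arrays of 2 rhesus macaques with occlusion of the middle cerebral artery: 12 ipsilateral and 12 contralateral cortex samples, 6 per side and animal, and 8 blood samples. Per the labels' protocols, cortex RNA was isolated with a column kit, blood RNA was depleted of globin transcripts, and 30 ng of each was labelled with Cy3 by a low-input amplification method. Spots were quantified with Agilent Feature Extraction 9.1, per the submitters' processing notes. The background correction, the averaging of spots and the probe filter are not given in the sources used here.

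The deposited values are on a log2 scale, as shown by their range of 5.67 to 19.36 and by array medians of 8.56 to 8.60. The sorted values of the arrays were nearly identical (median SD between arrays 0.012), and the highest value was the same number on 24 of the 32 arrays, which is what quantile normalization over both tissues together leaves. No label states that step. Such a normalization fixes the distribution of each array, so a change shared by most transcripts would not appear in these values. The table holds no detection calls, so how many probes lay above background is not known here.

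The table held 16476 probes, and all entered the tests. It names them by identifier, and the gene tables used here hold none of these identifiers. The planned rule was to test 1 probe per gene, and the planned gene lists and cell type markers covered stress, hypoxia, inflammation, neuronal and blood cell genes. None of these could be applied, and every probe was tested instead. Several probes may therefore measure the same gene, so counts of probes are not counts of genes. The rule for named items was planned too. For brain it took the largest rises and falls among probes past the threshold in the fit of both animals and in each animal alone. For blood it took those past the threshold with 1 sign in all 6 differences from T0. For both tissues it ranked probes by the smaller of their absolute changes, and for differences between animals by the size of the interaction. Without gene names, at most 2 probes that rose and 2 that fell are named for each comparison, the leading ones by that rule. A_01_P010726, A_01_P019368 and A_01_P004698 are named again in the comparison of tissues, a mention chosen after their values were seen.

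Tests used limma 3.58.1 in R 4.3.3, with lmFit, eBayes and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. Ipsilateral and contralateral cortex were compared over 24 arrays with the animal as a block. Effects within each animal and their difference came from a fit of 4 groups, and the coronal levels were compared by an interaction with the animal as a block. Blood was fitted over 8 arrays with time and animal, and the mean of 2, 3.5 and 4.5 h as well as each time was set against T0. Overlap between tissues was tested by Fisher's exact test against independent lists. In brain, p-values measure the spread between samples within 2 animals, not between animals, and samples of 1 side of 1 animal may differ for technical reasons only. The fit on means per animal is the exception, since it rests on how the side difference varied between the 2 animals. In blood, with 1 sample per animal and time, p-values measure how far the time courses of the 2 animals differed, together with array noise. These designs, lists, naming rules and most alternatives were chosen before the data were examined.

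In blood the replicate number is the animal, so the numbers pair the samples. Deviations from the time means correlated between samples of the same animal with r of 0.24 to 0.87. In brain, same-numbered samples of the 2 sides share the animal, the slide and the coronal level per the labels. Their deviations from the group means had a median correlation of 0.257, against -0.060 for other numbers of the same animal, and 7 of 12 pairs were over 0.1. The fit with the number as a block is an alternative. No arrays were identical, the smallest distance within a group (SD of the log2 difference) being 0.143. The ipsilateral array of S1 replicate 1 lay farthest from its group, at a mean distance of 0.383 against 0.208 to 0.316 for the other brain arrays.

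The fits were tested on simulated data for the same 16476 probes, drawn from the levels and spreads of these arrays with 200 probes changed. In brain, 95.0% of the 100 probes changed by log2 0.5 and 99.0% of the 100 changed by log2 1 were recovered, and 3.96% of the calls were false. In blood, 20.0% and 71.0% were recovered, and 5.21% of the calls were false. Noise was drawn independently for each probe and array. Each changed probe had the same effect in both animals and, in blood, at all later times. These rates therefore do not cover spread shared between probes or a change that differs between animals. The data gave far more calls, 3214 in brain and 2565 in blood, and recovery under this adjustment depends on the share of changed probes. The rates are thus not those of the real fits.

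Alternatives covered quantile normalization within a tissue, centring of arrays, a filter on dim probes, stricter thresholds, a minimum change, the variance model, blocks for pair, slide and level, single animals, and leaving out each pair or array. Added after the data were examined were a fit without the ipsilateral array of S1 replicate 1, classes of probes by tissue level, the overlap of rises against independent lists at single times and other thresholds, and a test of whether the blood change differed between animals.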

Results

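Gene expression was measured in cerebral cortex and blood of 2 male rhesus macaques, called S1 and S2, after occlusion of the middle cerebral artery, the vessel that supplies much of the lateral cortex. The animals were killed about 5.5 h after the occlusion began. Each gave 6 cortex samples from the occluded (ipsilateral) hemisphere and 6 from the opposite (contralateral) hemisphere, with 3 per side from each of coronal levels 2 and 3. Blood was drawn at T0, under anaesthesia and before surgery, and again at 2, 3.5 and 4.5 h after occlusion, with 1 sample per animal and time. The 32 samples were hybridised to single-colour Agilent arrays, 24 for brain and 8 for blood, and the value table held 16476 probes. Array medians lay between 8.56 and 8.60 on the log2 scale. The number of arrays limits the precision of each value. The table names probes by identifier and no source used here pairs these with genes, so results are given for probes.

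The first question was which transcripts differed between ipsilateral and contralateral cortex. No sham-operated series is in the labels, so occlusion and any effect of surgery on 1 side cannot be told apart. Probe A_01_P010726 was 33.0-fold brighter in ipsilateral cortex (log2 difference 5.04, SE 0.14) and was higher in all 12 same-numbered pairs of samples. In S1 it averaged 15.67 ± 0.32 (SD, n = 6) ipsilaterally and 10.99 ± 0.15 (n = 6) contralaterally. In S2 the corresponding values were 16.26 ± 0.54 and 10.86 ± 0.13 (n = 6 each). Probe A_01_P019368 rose 28.7-fold (log2 4.84, SE 0.13), also in all 12 pairs. The falls were smaller: A_01_P001272 was 1.81-fold lower (log2 -0.86, SE 0.14, lower in 12 of 12 pairs) and A_01_P016878 was 1.55-fold lower (log2 -0.63, SE 0.11, lower in 11 of 12 pairs). The limma adjusted p was 3.31e-18 for A_01_P010726, 8.54e-19 for A_01_P019368, 0.000174 for A_01_P001272 and 0.000176 for A_01_P016878. The level of A_01_P001272 also differed between the animals, with contralateral means of 10.52 ± 0.50 in S1 and 7.66 ± 0.18 in S2 (SD, n = 6 each). Its ipsilateral mean in S2 was 6.98, below the lower quartile of every array, so its fall there may be understated.

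**Figure D1:**
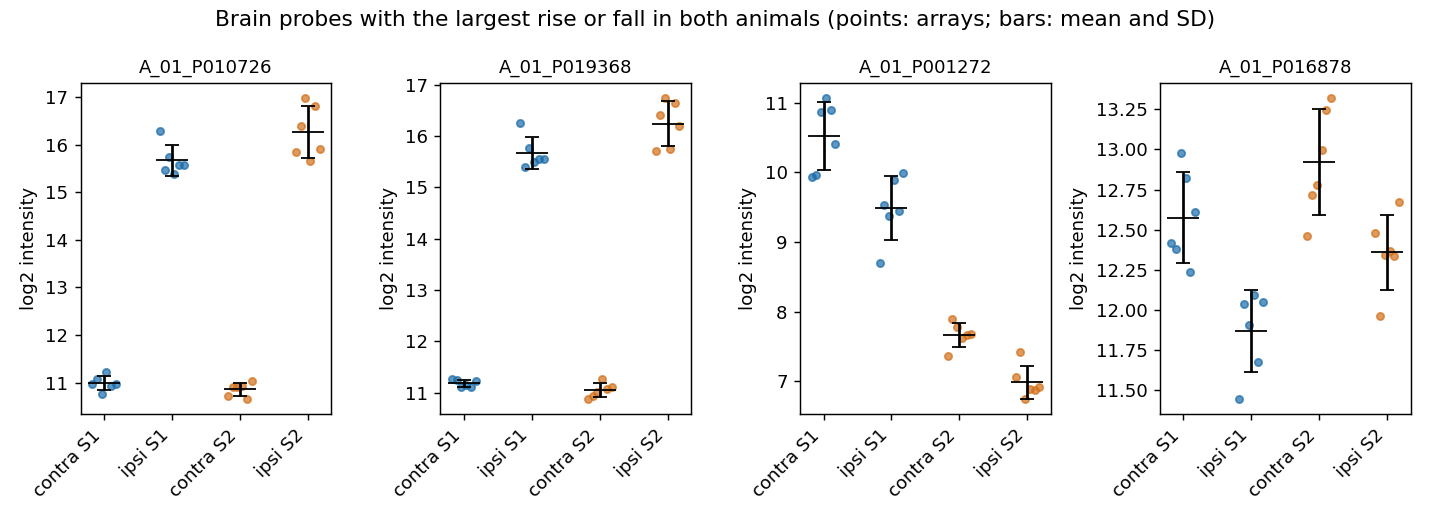
Log2 intensity (vertical axis) of 4 probes in the 4 brain groups (horizontal axis, 6 arrays each), with points for arrays, and bars for the mean and SD. A_01_P010726 and A_01_P019368 were higher in ipsilateral cortex in both animals; A_01_P001272 and A_01_P016878 were lower.

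Across the array, 3214 probes (19.5%) passed the threshold (limma with the animal as a block, adjusted p under 0.05), 1310 higher and 1904 lower in ipsilateral cortex. Most changes were small, with a median absolute log2 difference of 0.20 among these probes. Large changes ran in the upward direction: 53 probes rose and 0 fell by at least 2-fold in this fit of both animals, out of 5360 probes with an unadjusted limma p under 0.05 in either direction. At least 4-fold rises were seen for 16 probes and at least 8-fold rises for 6. At 1.41-fold the split was 202 higher to 11 lower. Of the 53 probes that rose 2-fold, 50 were higher in all 12 pairs. With slide as a block the count was 3588, and within the 6 slides taken singly, with 2 ipsilateral and 2 contralateral arrays each, between 51 and 53 of the 53 probes, which were chosen on these same arrays, were higher ipsilaterally. The count of probes past the threshold in a single slide ran from 2 to 329. Every ipsilateral array sat at other positions on its slide than every contralateral array, so position and side cannot be told apart. When each side was averaged per animal, leaving 2 pairs of values, limma called 56 probes, 55 higher and 1 lower. In that fit A_01_P001272 and A_01_P016878 kept their differences but not their calls (limma adjusted p 0.082 and 0.063).

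Strong rises found in 1 animal were mostly seen in the other. Of 46 probes that rose at least 2-fold in S1, 46 were higher ipsilaterally in S2, 37 passed the limma threshold there, and 35 rose at least 2-fold. Of 65 such probes in S2, 63 were higher in S1, 53 passed and 35 rose at least 2-fold. Each animal also had 1 probe that fell at least 2-fold, A_01_P001272 in S1 and A_01_P010510 in S2. The 53 probes from the fit of both animals were all higher in each, which that choice largely fixes, and 47 passed the threshold in each. A_01_P010726 rose 25.7-fold in S1 (log2 4.68, SE 0.18) and 42.4-fold in S2 (log2 5.41, SE 0.18). In the fit of 4 groups, S1 had 1609 probes past the threshold (744 higher, 865 lower) and S2 had 1045 (662 higher, 383 lower). That fit shares 1 estimate of spread per probe between the animals, so their lists are not independent of each other. The lists overlapped in 298 probes that rose in both animals, where independent lists would share 29.9, and in 153 that fell in both, against 20.1. Opposite calls were fewer than independent lists would give: 2 probes rose in S1 and fell in S2, against 17.3, and 5 fell in S1 and rose in S2, against 34.8. The side differences of the animals correlated across probes (Pearson r 0.675, Spearman rho 0.554), although probes are not independent replicates. Without the samples of replicate 3 the count in S1 was 650, with 371 higher and 279 lower, and the split also turned to more rises without replicate 1 (474 to 414) or replicate 2 (501 to 344). Without those of replicate 2 the count in S2 was 641.

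**Figure D2:**
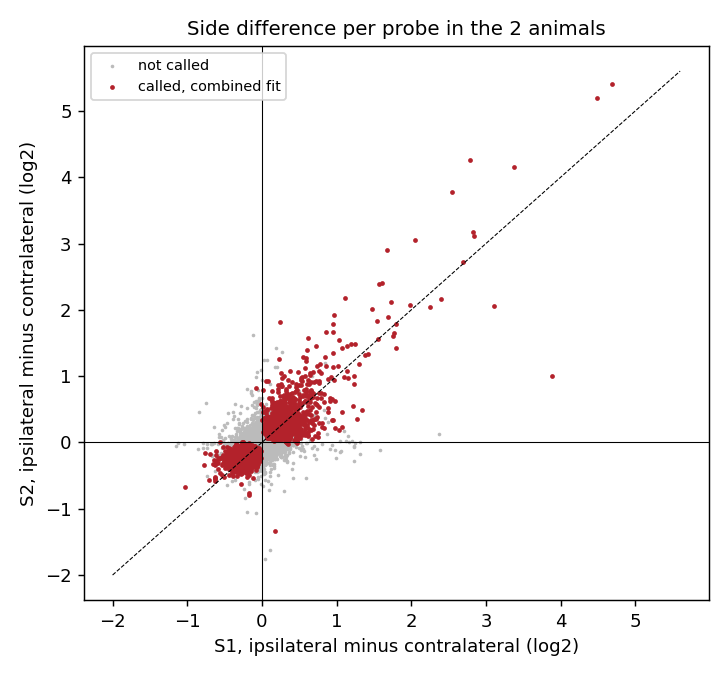
Ipsilateral minus contralateral log2 difference of each probe in S1 (horizontal axis) and in S2 (vertical axis), with red points past the threshold in the fit of both animals and a dashed line of equal values. The 53 probes that rose at least 2-fold lay above 0 in both animals.

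A further question was whether the animals responded differently. Probe A_01_P003187 rose in both animals but more in S2, by 19.1-fold (log2 4.26) against 6.87-fold (log2 2.78) in S1, a log2 difference of 1.48 (SE 0.26). Probe A_01_P004698 rose 3.53-fold in S2, in 6 of 6 pairs, while in S1 its log2 difference was 0.24 (SE 0.20), with 3 of 6 pairs higher. Probe A_01_P010510 fell in S2 (log2 -1.33, lower in 6 of 6 pairs) and had a log2 difference of 0.18 in S1. Probe A_01_P015370 rose in S1 (log2 0.41, 6 of 6 pairs) and fell in S2 (log2 -0.31, 6 of 6 pairs). The limma interaction gave an adjusted p of 0.021 for A_01_P003187, 0.022 for A_01_P004698, 0.019 for A_01_P010510 and 0.0049 for A_01_P015370. Leaving out 1 pair ended the call of A_01_P003187 in 3 settings (adjusted p up to 0.060) and of A_01_P004698 in 4 (up to 0.076). In all, 22 probes passed, with the S2 effect above that of S1 for 16 and below it for 6, and 1177 had an unadjusted p under 0.05 where 823.8 are expected by chance. The contralateral levels of the animals differed more than the ipsilateral levels for 15 of the 22, the named probes among them, and for 47.3% of all probes. For A_01_P004698 the contralateral means were 11.04 in S1 and 9.39 in S2, and the ipsilateral means were 11.27 and 11.21. Leaving out 1 pair at a time gave between 8 (without S2 replicate 4) and 19 probes.

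Samples came from coronal levels 2 and 3, and the side difference was set against this position. Ipsilateral cortex differed from contralateral cortex at both levels: 1981 probes passed at level 2 (945 higher, 1036 lower) and 708 at level 3 (440 higher, 268 lower). At least 2-fold rises numbered 55 at level 2 and 50 at level 3, and at least 2-fold falls 1 and 0. The difference between these effects was tested by a limma interaction, and 0 probes passed, with a smallest adjusted p of 0.248 and 938 probes at an unadjusted p under 0.05, where 823.8 are expected by chance. The lower count at level 3 is therefore not shown to be a difference between levels.

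Blood was compared with its own sample before surgery. Probe A_01_P012970 rose 37.4-fold on average over the later times (log2 5.23, SE 0.50) and A_01_P006028 rose 25.6-fold (log2 4.68, SE 0.45). Both were higher than T0 in 6 of 6 differences (3 times in 2 animals). A_01_P012970 went from 8.23 to 14.93 between T0 and 4.5 h in S1 and from 8.04 to 12.58 in S2. Probe A_01_P001085 was 3.05-fold lower (log2 -1.61, SE 0.28) and A_01_P015920 was 2.86-fold lower (log2 -1.52, SE 0.36), each in 6 of 6 differences. The naming rule required 1 sign in all 6 differences, so these counts lend the 4 probes no support. The 3 differences of an animal also share its T0 sample. The limma adjusted p was 0.00839 for A_01_P012970, 0.00838 for A_01_P006028, 0.024 for A_01_P001085 and 0.044 for A_01_P015920. All 4 lost the call without the animal block (limma adjusted p 0.164, 0.196, 0.265 and 0.462 in that order) and without either sample at 3.5 h. Over 13 settings A_01_P001085 lost it in 6 and A_01_P015920 in 7. None of these 4 passed the threshold in brain, where their limma adjusted p was 0.701, 0.772, 0.073 and 0.865 in the order given. In the brain groups A_01_P006028 averaged 6.6 to 7.0, below the lower quartile of every array, so a change there may not show.

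**Figure D3:**
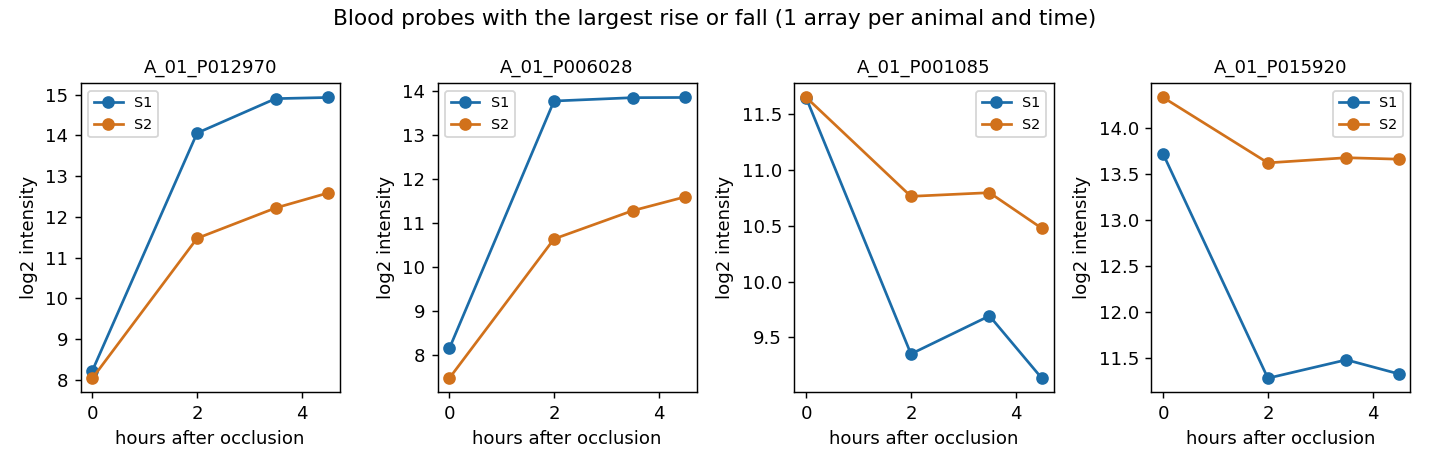
Log2 intensity (vertical axis) of 4 probes in blood against hours after occlusion (horizontal axis), with 1 array per animal and time, where 0 is the sample before surgery. A_01_P012970 and A_01_P006028 rose, and A_01_P001085 and A_01_P015920 fell, with larger changes in S1 than in S2.

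In total 2565 probes (15.6%) passed in blood, 1223 higher and 1342 lower than T0 (limma, animal as a block, mean of 3 times). This split turned to more rises at an adjusted p under 0.01 (181 higher, 42 lower) and in most settings that left out 1 array. Larger changes were mostly rises: 436 probes rose and 81 fell by at least 2-fold, and all 71 that changed at least 4-fold rose. Of the 2565 probes, which were chosen on these same arrays, 2544 had 1 sign in all 6 differences. The count rested on the pairing by animal and on single arrays. Without the animal block 9 probes passed (2531 at an unadjusted p under 0.05), without the S1 sample at 3.5 h 20 passed, and without the T0 sample of S2, when S1 alone supplies T0, 7062 passed. Time, the length of anaesthesia, surgery and occlusion changed together in blood, and no sham-operated series is in the labels.

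By time, 287 probes differed from T0 at 2 h (245 higher, 42 lower), 1517 at 3.5 h (792 higher, 725 lower) and 1699 at 4.5 h (837 higher, 862 lower). Probe A_01_P012970 rose by log2 4.63 at 2 h, 5.43 at 3.5 h and 5.62 at 4.5 h. Probe A_01_P001085 had log2 differences of -1.59, -1.40 and -1.84 at these times, and only the last passed (limma adjusted p 0.090, 0.062 and 0.035). Set against 2 h directly, 0 probes differed at 4.5 h by limma, with 1271 at an unadjusted p under 0.05 and a smallest adjusted p of 0.591. The rise in the counts over time is therefore not shown to be a change between these times. Without the animal block 0 probes passed at each of 2, 3.5 and 4.5 h (limma, 1596, 1742 and 1841 at an unadjusted p under 0.05), and leaving out a single array gave from 0 to 6191, 6170 and 6546 probes.

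The series asks which transcripts change in both tissues. Probe A_01_P001228 rose 3.05-fold in ipsilateral cortex (log2 1.61, SE 0.19, higher in 12 of 12 pairs) and 7.12-fold in blood (log2 2.83, SE 0.22, 6 of 6 differences). Probe A_01_P004760 rose by log2 1.44 in brain (SE 0.26, 11 of 12 pairs), with 0.96 in S1 (limma adjusted p 0.080) and 1.92 in S2 (0.00084), and by log2 1.44 in blood (SE 0.16, 6 of 6 differences). A_01_P010726, the probe with the largest rise in cortex, was also higher in blood (log2 1.04, SE 0.24, limma adjusted p 0.041), by 1.43 in S1 and 0.65 in S2. At 2, 3.5 and 4.5 h taken singly it did not pass (limma adjusted p 0.115, 0.127 and 0.061), and it lost the call in 7 of 13 blood settings. Probe A_01_P019368, the other leading rise in cortex, did not pass in blood (log2 0.84, SE 0.30, limma adjusted p 0.109). In ipsilateral cortex A_01_P010726 and A_01_P019368 both averaged 15.67 in S1, and 16.26 and 16.24 in S2. Without gene names it is not known whether they measure the same transcript, so their blood calls need not be a contrast between transcripts. Probe A_01_P019205 fell in both tissues (log2 -0.51 in brain, -1.27 in blood), as did A_01_P010444 (log2 -0.41 in brain, -0.50 in blood). The limma adjusted p in brain and blood was 1.44e-06 and 0.00514 for A_01_P001228, 0.000379 and 0.010 for A_01_P004760, 0.000146 and 0.043 for A_01_P019205, and 0.00242 and 0.021 for A_01_P010444. None of the 5 probes named here as called in both tissues kept its blood call without the animal block. Over 13 blood settings A_01_P019205 lost it in 7 and A_01_P010444 in 6, and the blood fall of A_01_P019205 was log2 -1.94 in S1 and -0.59 in S2. On means per animal, A_01_P004760, A_01_P019205 and A_01_P010444 lost the call in brain (limma adjusted p 0.111, 0.062 and 0.081).

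**Figure D4:**
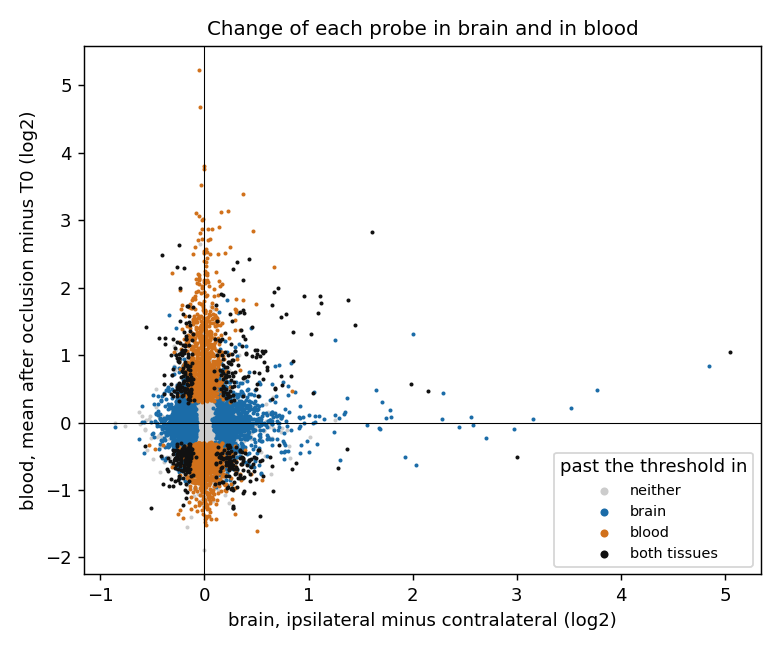
Log2 change of each probe in brain, ipsilateral minus contralateral (horizontal axis), and in blood, mean after occlusion minus T0 (vertical axis), coloured by the tissue in which it passed the threshold. Of the probes past it in both, 131 rose in both and 142 fell in both.

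For the mean of the later times, with all blood arrays in the fit, the shared rises exceeded the overlap of independent lists, and the shared falls did not. In most settings that left out 1 blood array, the excess of all rises no longer passed Fisher's exact test. The ratio of shared rises to independent lists was then 0.629 (without the S1 sample at 3.5 h) to 1.37 (without the T0 sample of S2), against 1.35 with all arrays. Of 1310 probes higher in ipsilateral cortex and 1223 higher in blood, 131 were shared, against 97.2 for independent lists (Fisher's exact test, 2-sided, p 0.000348, adjusted p 0.00104 over 6 tests). Falls were shared by 142 probes against 155.1 (Fisher's exact test, adjusted p 0.318). Opposite directions were taken by 121 probes that rose in brain and fell in blood, against 106.7, and by 126 that fell in brain and rose in blood, against 141.3 (Fisher's exact test, adjusted p 0.245 for each). Among changes of at least 2-fold, 8 probes rose in both tissues, against 1.40 (adjusted p 0.000422 by Fisher's exact test). In the fit of both animals these 8 rose by log2 1.03 to 5.04 in brain, and 6 of them were higher in all 12 brain pairs. The smallest of these brain rises, that of A_01_P004698, was log2 0.24 in S1 (limma adjusted p 0.502) and 1.82 in S2, and some others were under 2-fold in 1 animal. In blood the 8 rose by log2 1.04 to 2.83. Taken time by time, the shared rises lay closer to independent lists: 24 against 19.5 at 2 h, 73 against 63.0 at 3.5 h and 77 against 66.5 at 4.5 h (Fisher's exact test, adjusted p 0.315, 0.223 and 0.220 over 30 tests). With an adjusted p under 0.01 in each tissue there were 10 against 8.34 (Fisher's exact test, adjusted p 0.512). The 2-fold rises shared at these times numbered 4, 6 and 6, against 0.537, 1.20 and 1.30 (Fisher's exact test, adjusted p 0.00467, 0.00408 and 0.00448). With an adjusted p under 0.01 in each tissue, 2 probes rose at least 2-fold in both, against 0.436 (Fisher's exact test, adjusted p 0.101). In most settings that left out 1 blood array fewer 2-fold rises were shared, and without the S1 sample at 3.5 h their excess did not pass. Across all probes the changes of the tissues were nearly uncorrelated (Pearson r 0.031, Spearman rho -0.014). Probes are not independent replicates, and without the S1 blood sample at 3.5 h the number changed in the same direction in both tissues fell from 273 to 1.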

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

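The test of whether the blood change differed between the animals, and the comparison of later times between the animals, were chosen after these differences were seen.

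The side effect in brain differed between the animals for 22 probes by limma's interaction. The S2 minus S1 difference (log2) was 1.58 for A_01_P004698, 1.48 for A_01_P003187, -1.51 for A_01_P010510 and -0.72 for A_01_P015370. In the contralateral cortex of S1, replicate 4 stood apart for A_01_P004698, at 11.71 against 10.78 to 11.03 in the other 5 samples (gap over range 0.733), and for A_01_P010510, at 7.97 against 8.71 to 9.04 (0.697). In the contralateral cortex of S2, the mean distance of replicate 1 to its group was 0.287 against 0.208 to 0.231 (0.708). Of 52 groups of 6 samples examined, 3 were beyond Dixon's critical value, where chance gives about 1 in 20, or 2.6.

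The change in blood differed between the animals for 386 probes (limma, 3 later times taken as 1 state; 3857 at an unadjusted p under 0.05), with S2 above S1 for 123 and below for 263. Each animal has a single T0 sample, which has no spread of its own, so this test takes the spread from serial samples of 1 animal and assumes that T0 varies like them. Its count is a description of these samples. Of the 517 probes that changed at least 2-fold, 488 changed more in S1, with a median ratio of log2 differences of 1.79. A T0 sample standing apart in 1 animal would place the difference at T0 if the animals otherwise had equal levels. The median S1 minus S2 difference in the direction of change was 0.11 at T0 and averaged 0.89 over the later times. With 1 T0 sample per animal, equal levels cannot be shown, so these values do not decide whether a T0 sample stood apart. Compression of the signal on the slide of S2 stays open: the ratio of S1 to S2 for the difference between 4.5 and 2 h was 0.967, yet 0 probes passed the threshold between those times (limma, 1271 at an unadjusted p under 0.05), so this ratio mostly measures spread between arrays. Each animal's blood lay on its own slide, so slide and animal cannot be told apart, and a difference in response between the animals may remain as an untested hypothesis.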

How the results depend on the processing

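The fit without the ipsilateral array of S1 replicate 1 was chosen after the data were seen and gave 3108 in brain, 1304 in S1 and 17 for the animal difference. Of 196 alternative counts, 113 stayed within 1.5 times and 83 moved further. The 113 include every setting of the level difference and of 4.5 h against 2 h, whose counts were 0 throughout. No named probe changed sign, which the naming rules for brain and blood largely fix. Stricter settings lowered counts by construction. At an adjusted p under 0.01 they were 1509 in brain, 523 in S1, 511 in S2, 5 for the animal difference, 223 in blood, and 0, 19 and 13 at 2, 3.5 and 4.5 h. With a 2-fold minimum they were 53, 47, 66, 4, 517, 177, 449 and 527. Leaving out the probes below the median level, which tests fewer, gave 1686 in brain, 902 in S1 and 505 in S2. The brain count was 1634 from S1 alone, 819 from S2 alone, 1936 without any block and 56 on means per animal. With a replicate block (paired by number) it was 3682 in brain, 2128 in S1, 1258 in S2 and 31 for the animal difference. Of the calls without it, 227 of 3214, 135 of 1609, 114 of 1045 and 4 of 22 were lost, none of them a named probe. Without the animal block, blood gave 9, and 0 at each time; the lost calls are not weaker effects. Only 4 of 12 ipsilateral arrays correlated best with their own number.

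For both tissues, 273 probes changed in the same direction. This became 177 without dim probes, 11 at 0.01, 665 at 0.1, 0 without the block in blood, and 27 or 139 with 2 h or 3.5 h as the blood comparison.

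Leaving out 1 pair gave 2393 to 3837 in brain, 650 to 1439 in S1, 641 to 1351 in S2, 8 to 19 for the animal difference and 0 to 0 for the level difference. In S1, replicates 1, 2, 3 and 5 moved the count by over 1.5 times (888, 845, 650, 812), as did replicate 2 in S2 (641). For the animal difference these were S1 replicates 1 to 4 (14, 14, 11, 11) and S2 replicates 1, 2 and 4 (12, 13, 8). Leaving out 1 blood array gave 20 to 7062 for the mean, 0 to 6191 at 2 h, 0 to 6170 at 3.5 h, 0 to 6546 at 4.5 h, 0 to 0 for 4.5 against 2 h, and 1 to 813 in both tissues. For the mean, S2 gave 7062 without T0, 224 without 2 h, 99 without 3.5 h and 1580 without 4.5 h, and S1 gave 1478, 166, 20 and 797. A lone sample is then assumed to vary like the others.

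Named probes lost their call in 8 of 192 brain settings, 44 of 117 blood settings and 7 of 72 settings of the animal difference. A_01_P001272 was not called without any block (limma adjusted p 0.354, range 2.26e-05 to 0.354). On means per animal 5 of the 8 brain probes lost the call: A_01_P001272 (0.082), A_01_P016878 (0.063), A_01_P004760 (0.111), A_01_P019205 (0.062) and A_01_P010444 (0.081). In S1 alone A_01_P004760 (0.158) and A_01_P010444 (0.084) lost it. All 9 blood probes lost it without the animal block. A_01_P003187 was not called without S1 replicate 1 or 4 or S2 replicate 4, nor A_01_P004698 without S1 replicate 3 or S2 replicates 1, 2 or 4. Not run, for want of gene names, were the mean of a gene's probes, 1 probe per gene, and the gene list tests. Signal over background is not known here.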

Other observations

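The classes of probes by tissue level, the floor test and the test of the share of blood were chosen after related results were seen.

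Probes were grouped by whether T0 blood or contralateral cortex was at least 4-fold brighter. In the brain comparison, 170 of 1353 blood-enriched probes rose and 75 fell, while 86 of 1683 brain-enriched probes rose and 261 fell. limma's camera gave an adjusted p of 0.000177 for the blood-enriched and 0.0203 for the brain-enriched probes, and an adjusted p of 0.251 for each with an estimated correlation, at which neither call held. The median side difference was 0.02 and -0.07 (log2). The contralateral level both defines these classes and is the reference of the comparison, which favours these directions. With levels averaged over baseline and later samples, the counts were 160 to 82 and 110 to 247, and camera's adjusted p was 0.00177 for the blood-enriched and 0.0877 for the brain-enriched probes, which ended the latter call (0.333 for each with an estimated correlation). In blood, the blood-enriched probes split evenly (283 rose, 284 fell), their median (-0.13) and mean (0.02) differed in sign, and with the averaged levels the split was 388 to 212, so that it depends on the definition.

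In the fit of both animals, every brain change of at least 2-fold past the threshold was a rise, 53 to 0, while S1, S2 and coronal level 2 taken singly each had 1 such fall. A floor that hides falls would act on dim probes, and among the 4745 probes with a brain mean of at least 10, 27 rose and 0 fell 2-fold. As this fit held 0 such falls in all, 0 in any subset was fixed. The split therefore shows only that rises of this size also occurred among bright probes, and does not decide about a floor. No single pair carries the pattern, since at least 48 rises and at most 0 falls were found with any 1 pair left out. A shift of all probes by 0.52 (log2) would be needed to balance 2-fold rises and falls, but joint quantile normalization fixes the median of all probes, so a global fall of transcripts cannot be excluded from these values. A rise of a small set of transcripts in ipsilateral cortex may therefore be real without showing that no transcript fell as much.

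With probes called at an adjusted p under 0.01, shared 2-fold rises did not pass Fisher's exact test. The same held without the S1 blood sample at 3.5 h. With all arrays and the main threshold, the 8 probes that rose at least 2-fold in both tissues exceeded independent lists. Of 10000 random lists matched on blood level and spread, a share of 0.0011 held as many (mean 2.32), which argues against bright or variable probes as the whole cause. Blood left in ipsilateral tissue cannot raise a probe above its level in blood, and 3 of the 8 were dimmer in blood than in ipsilateral cortex, A_01_P004760 by a log2 difference of only -0.0036, which is a tie. That is fewer than the 4 set beforehand as enough to exclude it. This comparison of levels, and the share of blood that follows, use intensities that look jointly normalized, so neither measures amounts of RNA. The blood RNA was also depleted of globin transcripts. On these intensities, the lowest share of blood that would give the rise of any of the 8 is 18.2%, at which blood-enriched probes would rise by a median of 1.23 (log2). Their medians were 0.01 in S1 (quartiles -0.07 and 0.12) and 0.04 in S2 (-0.03 and 0.14), which argues against blood as sampled here, while cells entering the tissue with another profile, and a response common to both tissues, remain untested and may contribute.

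Other splits of the samples bear on whether chance gives such counts. For the brain comparison 1 of 100 splits that swapped sides within pairs, the real one, reached 3214 probes (highest other 950). In S1 it was 1 of 32 (1609, highest other 52) and in S2 1 of 32 (1045, highest other 566). For the animal difference, with the replicate block, it was 1 of 100 (31, highest other 2). For these 4 counts chance assignment of samples can be excluded at a share of 0.05, but samples within an animal may be repeats, and with 1 animal on each side of the animal difference, chance between animals is not excluded. For the coronal levels the real count was 0, which all 100 of 100 splits reach by necessity (highest other 1), so the splits decide nothing. In blood, 16 choices of 1 array per animal as T0 are too few for a share under 0.05: the real choice gave 3247 probes with the later times as 1 state, 1 of the 16 gave as many, and the highest other was 0.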
